A study of Nematostella vectensis with 6 samples.

How the data were processed

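RNA abundance was measured in the starlet sea anemone, Nematostella vectensis, on 6 custom Agilent arrays with 60-base probes, 2 arrays for each of 3 stages of tentacle growth. Per the labels, animals were raised at 16 °C and a salinity of 12 ppt to day 8 (tentacle buds of late planula larvae), day 14 (growing tentacles of primary polyps) or day 30 (mature tentacles). Per the labels' protocols, large pools of animals were dissected for a sample by severing the body at the tentacle base, and total RNA of the oral fragment and of the remaining body column was pooled separately. On every array the Cy5 (red) channel held the oral, tentacle-bearing fragment and the Cy3 (green) channel the body column of the same stage. The dyes were not exchanged, so a dye effect of a probe is part of every ratio, and a constant one cancels only in differences between stages. The labels call the 2 arrays of a stage biological replicates. The arrays of buds and growing tentacles were on 1 slide and those of mature tentacles on the other, so slide and mature stage cannot be told apart.

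Per the file headers, the authors scanned the arrays with Agilent Feature Extraction 10.5.1.1, and the deposited scanner files give each spot's mean and background intensity in both channels on a linear scale. The same deposited files give a processed intensity, background-subtracted and dye-normalized per the file headers, and a log10 ratio of red over green. Per the file headers, yes-or-no flags mark spots well above background, saturated or an outlier. Each deposited array held 45220 spots, of which 1417 were controls and 43803 carried probes of 43788 distinct sequences. The series' deposited value table holds log2 ratios of red over green made with limma, per the submitters' processing notes (version not given in the sources used here). Recomputation from the scanner intensities gave the same values where background was subtracted and loess applied within each array. Its column medians were 0.01, -0.00, 0.01, 0.01, -0.00 and 0.01 in the order buds, growing and mature, and between 43 and 2775 spots of an array had no value. The table's scale, direction and centring were settled by that recomputation.

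From the mean and background intensities, the background was corrected with normexp (offset 50), ratios were normalized by loess within each array with controls at weight 0, and controls and outlier spots were left out (limma 3.58.1 in R 4.3.3). The offset is added to both channels and pulls the ratios of dim probes towards 0. Median green signals were 42.2 to 53.3 over median backgrounds of 20 to 22, so this bears on many probes. Spots of one sequence were averaged. Probes well above background in at least 1 channel on at least 2 arrays were kept, 31244 or 71.4% of the sequences. Of the spots that carried probes, 62.6% to 78.2% of an array were well above background in the red channel and 59.6% to 71.5% in the green one, and 0 were saturated. The number of arrays limits the precision. One limma model with a mean for each stage was fitted to the log2 ratios of all 6 arrays, which leaves 3 residual degrees of freedom and adds 3.08 prior ones. Each stage's ratio and the mean of the 3 stages were tested against 0, and differences between stages were tested as contrasts. Every adjusted p is limma's moderated test with Benjamini-Hochberg adjustment over all probes tested, and a probe is called where it lies under 0.05. Channel levels came from the ratios and mean intensities after loess and Aquantile scaling between arrays. They are open to dye bias, and where every array of one fragment was not well above background the fold is given as a bound ("at least").

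None of the probe names could be paired with genes, since 0 of them matched the RefSeq gene table used (assembly jaNemVect1.1). Lists of gene descriptions and of cell type markers, chosen before the data were examined, could therefore not be applied. In their place the probes were sorted into protein families, chosen after the files had been opened and before any ratio was tested. For this, 77 hand-written query sequences of textbook proteins were searched with BLAST 2.17.0 (blastp-short) against the translations of the 3 forward frames of each probe, and matches of at least 26 bits were kept. The opposite strand served as a background, and of 49 families 42 with at most 0.2 opposite-strand matches per forward match were kept. These held 504 probes, against 18 matches on the opposite strand, and 451 of the probes were measured. The thrombospondin query ended in an EGF-like stretch, which 5 of its 32 probes matched, 2 of them measured, and the family was also tested without them, a choice made after the results had been seen. A family match is a short stretch of similar protein sequence and not a gene name, and several probes can report one transcript. Across all probes, 676 groups of probes shared at least 30 bases. Of the 522 such groups with at least 2 measured probes, 480 had one call for every member in the mean of the stages and 2 held opposite calls.

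Families of at least 5 measured probes, 23 in all, were tested with camera at a preset correlation of 0.01 between probes, which compares a family with all other probes. The same test with an estimated correlation, and fry, were run as alternatives. The fry test asks whether a family's probes move on balance one way, its mixed form whether they change in either direction, and neither compares the family with other probes. Family p-values were adjusted over the 23 families, and counts of members are also given adjusted over the list alone. The tests, the filter, the threshold and most of the alternatives were fixed before the data were examined. The rule for named items was to give at most 2 probe names that rose and 2 that fell per comparison, those with the largest ratios of one sign on every array of the comparison, and of each family up to 3 highest and 3 lowest called members in the mean of the stages. Family members are given by the translated sequence they matched with. Examples among them, and members named for a single stage, were chosen after their values were seen.

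Alternatives fixed before the data were examined covered the background, the normalization, the dim filter, the model, the authors' own ratios and the leaving out of each array in turn. Removal of GC and surface trends, averaging of overlapping probes and the leaving out of both buds arrays were added later. A further addition was to leave out spots beside bright specks, defined as a local background over 1.5 times the array's median in either channel. There were 189 such spots, 9 on growing array 1, 96 on growing array 2 and 84 on mature array 2. On growing array 2 they gave net intensities down to -13926 in the red and -16584 in the green channel, and with them the background mean estimated by normexp was -284 and -196, against -1.43 and 1.38 without them. The median absolute log2 ratio of that array was 0.0392, against 0.119 to 0.198 on the other arrays. This alternative and its factor were chosen after the counts and their alternatives had been seen, and no other factor was fitted. The values without these spots had for a time been taken as the leading ones, before the fit laid down in advance was put back.

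The steps were tested on simulated ratios with known changes in 31232 probes. In the mean of the stages, 59.7% of changes of 0.5 and 97.0% of changes of 1 on the log2 scale were recovered. In single stages 67.2% to 73.1% of changes of 1 were recovered, and in differences between stages 16.4% to 28.4% of changes of 1 and 86.4% to 90.9% of changes of 2. Of the simulated calls in the mean 3.93% were false, and of those in buds 9.6%. A family of 30 probes shifted by 0.3 was found by camera, and 0 unshifted families were called. Probes were simulated as independent, each with one spread on all arrays, and few of them were changed. The rates therefore do not cover correlated probes or a wider spread of the buds arrays. Python 3.11.15 with pandas 2.3.3, Biopython 1.88 and matplotlib 3.10.9 was used for the family search and the figures.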

Results

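Tentacles of Nematostella grow as buds around the mouth of the larva and lengthen in the polyp. The arrays addressed which transcripts differ between the tentacle-bearing oral fragment and the body column, and whether that difference changes from buds through growing to mature tentacles. Each of the 3 stages had 2 arrays, and each array set an oral fragment directly against the body column of its stage. Positive log2 ratios stand for more signal in the tentacle fragment. Over the 31244 probes measured, Pearson's correlation between the 2 arrays of a stage was 0.544 in buds, 0.852 in growing and 0.869 in mature tentacles, across probes, which are not independent replicates. Spearman's correlation of these pairs was 0.217, 0.669 and 0.698, so by rank the buds arrays agreed poorly. With the 4 arrays of the other stages buds array 1 correlated at 0.495 to 0.708 and buds array 2 at 0.706 to 0.827, the highest with mature array 1. Buds array 1 had the lower value with each of the 4 by Pearson's correlation, though by Spearman's it was closer to growing array 2 (0.501 against 0.474). Over the 6531 probes called in the mean of the stages the correlations were 0.879, 0.913 and 0.962. Of these probes 95.0%, 98.5% and 97.9% had one sign on both arrays. They were called from these same arrays, and the call favours probes whose ratios agree. These values are therefore no separate measure of how well the arrays of a stage agreed.

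Over the mean of the 3 stages, more probes of the homeodomain, thrombospondin type 1 repeat and tubulin families were called higher in tentacle fragments than were called lower, although tubulins had 1 each way with arrays scaled to equal spread. Both probes of Wnt ligands were higher, though only 1 was called with arrays scaled to equal spread, and probes of EGF-like repeats were called in both directions. Of 36 measured homeodomain probes, which report DNA-binding regulators of patterning and cell identity, 18 rose and 6 fell (18 and 8 adjusted over the list alone, 3 and 2 with arrays scaled to equal spread). The highest matched the Pax6 query with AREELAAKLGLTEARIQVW, at a log2 ratio of 1.85 ± 0.13 (SE, 6 arrays; adjusted p = 3.29e-04). The lowest matched the Antp query with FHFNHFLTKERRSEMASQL, at -2.35 ± 0.07 (adjusted p = 2.41e-05), and was lower by a like amount in each stage (-2.39, -2.28 and -2.39). The Wnt family encodes secreted signals of axial patterning, and both of its measured probes rose. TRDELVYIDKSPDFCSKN stood at 1.82 ± 0.10, and the other, not well above background in the body column on any array, was at least 1.23-fold higher (adjusted p = 0.0163). Their size depended on the processing, with a median of 1.06 as fitted, 1.87 with the authors' ratios and 2.26 with Agilent's processed signals.

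Other families of regulators held fewer calls. Of 5 probes of Sox and HMG box proteins, which bend DNA at their target genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, with limma as the test), up to 1.04 ± 0.05 for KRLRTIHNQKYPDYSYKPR. Of 29 C2H2 zinc finger probes 6 rose and 3 fell, with a median of -0.02 that became 0.18 under median centring (14 higher, 1 lower) and 0.08 with Agilent's processed signals, a mean of 0.17, and a highest value of 1.88 ± 0.12 for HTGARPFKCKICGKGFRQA. Of 8 forkhead probes 4 rose and 1 fell. The one that fell, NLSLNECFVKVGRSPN--GKG, stood at -2.09 ± 0.15 (adjusted p = 3.69e-04). This mean is not exact, since its tentacle signal was well above background on 4 of 6 arrays and on 0 of 2 in mature tentacles. Of 7 T-box probes 3 rose and 1 fell, between 1.25 ± 0.14 for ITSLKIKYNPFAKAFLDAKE and -0.55 for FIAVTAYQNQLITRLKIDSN. With arrays scaled to equal spread limma called 1 Sox probe higher, 2 forkhead probes higher and 1 lower, and 1 T-box probe each way. Of C2H2 probes it called 0 higher and 1 lower, with 11 at an unadjusted p under 0.05. Each family member named with a value for the mean had one sign on all 6 arrays.

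Among structural and extracellular proteins, 11 of 28 probes of the thrombospondin type 1 repeat family, modules of secreted and adhesive proteins, rose and 3 fell (14 and 4 adjusted over the list alone, 4 and 2 with scaled arrays). Of these 28, 2 matched an EGF-like stretch at the end of the query and not a type 1 repeat, and without them 10 of 26 rose and 3 fell (13 and 4 adjusted over the list alone). The highest, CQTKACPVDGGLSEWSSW and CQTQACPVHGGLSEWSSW, reached 2.39 ± 0.10 and 2.24 ± 0.09, and WSSWGACSKTCG fell by 1.36. Of 29 tubulin probes, for the subunits of microtubules and cilia, 10 rose and 2 fell (13 and 7 adjusted over the list alone, 23 and 2 under median centring). The highest 3 matched alpha tubulin, with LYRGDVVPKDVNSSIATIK at 1.87 ± 0.12, and the beta tubulin stretch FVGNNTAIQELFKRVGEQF stood at -1.17 ± 0.05. EGF-like repeats, common in adhesion and signalling proteins, went both ways. Of 38 probes 8 rose and 7 fell, with a median of 0.08 and a mean of -0.08. These counts were 14 and 6 under median centring, 2 and 5 with scaled arrays, and 12 and 7 with spots beside bright specks left out. The lowest was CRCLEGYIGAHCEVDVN at -2.56 ± 0.11 (adjusted p = 5.34e-05). Of 54 core histone probes, in 33 groups by shared bases, 12 rose by 0.28 to 0.47 and 0 fell (12 and 0 adjusted over the list alone, with limma as the test). This count was 40 under median centring, and with scaled arrays 0 were called by limma, with 24 at an unadjusted p under 0.05. Of 9 probes of EF-hand proteins, which bind calcium, 4 rose and 1 fell (in limma 8 and 0 under median centring, 1 and 0 with scaled arrays), with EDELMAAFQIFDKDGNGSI at 1.48 ± 0.05. Of 56 protein kinase probes 10 fell and 2 rose, by small amounts, and of 29 small GTPase probes 4 fell and 1 rose. The medians of these last 2 families, -0.05 and -0.08, turned to 0.18 and 0.38 under median centring, and the calls to 22 higher and 3 lower for kinases and 14 higher and 1 lower for small GTPases.

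Against all other probes, camera called 4 of the 23 families tested in the mean, all of them higher. They were core histones (median 0.17, adjusted p = 1.74e-05), Sox and HMG box (0.57, adjusted p = 0.00561), homeodomain (0.17, adjusted p = 0.0210) and the thrombospondin family (0.16, adjusted p = 0.0263, and 0.0417 without its 2 EGF-like matches). With an estimated correlation 0 of the 23 were called, and each of these 4 had an adjusted p of 0.749. Under median centring core histones were still called (adjusted p = 9.68e-04), but Sox and HMG box (0.257), homeodomain (0.140) and the thrombospondin family (0.761) were not. These medians stayed above 0 under every scaling tried and without a dim filter but varied in size, from 0.12 to 0.73 for core histones, 0.15 to 1.19 for Sox and HMG box, 0.08 to 0.54 for homeodomain and 0.06 to 0.70 for the thrombospondin family. By fry, which does not compare with other probes, 8 families moved on balance one way, among them homeodomain (adjusted p = 0.00824) but not core histones (adjusted p = 0.0854).

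**Figure D1:**
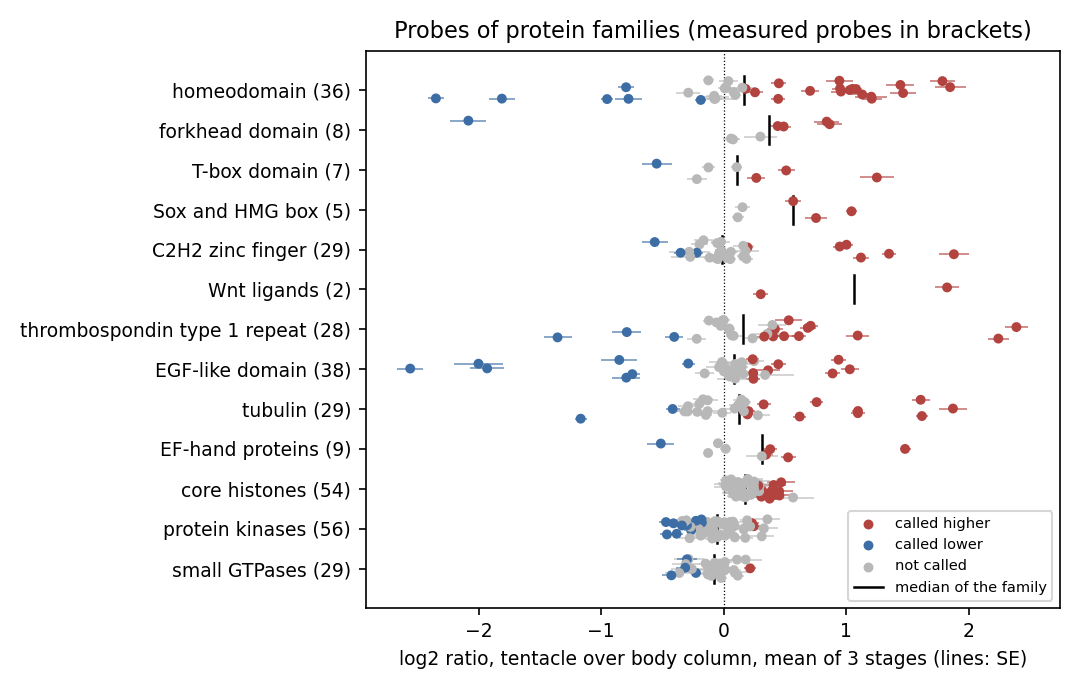
Log2 ratios of tentacle over body column as the mean of 3 stages, 1 point per measured probe of 13 protein families, with lines for the SE, colour for probes called higher or lower by limma, and a black bar for the family median. Homeodomain probes range from -2.35 to 1.85, and the small negative medians of C2H2 zinc fingers, protein kinases and small GTPases turn positive under median centring.

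In the mean of the stages 6531 probes (20.9% of those tested) were called, 3785 higher and 2746 lower. Their median absolute log2 ratio was 0.42, and 885 of them differed at least 2-fold (593 higher, 292 lower). These sizes hold for the offset used, which pulls the ratios of dim probes towards 0. The highest were SB_3275_95 at 3.57 ± 0.20 (11.9-fold, adjusted p = 1.44e-04) and JGI_85362_297 at 3.52 ± 0.11 (11.4-fold, adjusted p = 2.48e-05). The lowest were SB_135_218 at -3.30 ± 0.06 (adjusted p = 1.73e-05) and SB_10096_111 at -3.12 ± 0.13 (adjusted p = 6.31e-05), all with one sign on all 6 arrays. The count became 15822 under median centring (14178 higher, 1644 lower, with the median of all probes at 0.22 in place of 0.01) and 2100 with arrays scaled to equal spread, and the share of higher calls was 58.0%, against 89.6% under median centring and 68.0% with Agilent's processed signals. It was 12278 without buds array 1, 3303 and 4312 without growing array 1 or 2, and 3169 and 3225 without mature array 1 or 2.

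In buds, probes of homeodomain, Sox, C2H2, forkhead and T-box regulators were among those called higher in the tentacle fragment, and of these 5 families camera called homeodomain and Sox (each with an adjusted p of 0.710 with an estimated correlation). Of 36 homeodomain probes 15 rose and 5 fell, with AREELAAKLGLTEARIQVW at 2.24 ± 0.22 (adjusted p = 0.00329). Each SE here is that of a 2-array mean, with the spread taken from the arrays of all stages. The SD between replicates was 0.307 in buds, against 0.144 in growing and 0.145 in mature tentacles. The SEs and p-values given for buds are therefore likely too small. Of the T-box probes 2 of 7 rose and 0 fell (4 and 0 adjusted over the list alone, with limma as the test), and the higher, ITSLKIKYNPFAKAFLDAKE, stood at 2.24 ± 0.24 (adjusted p = 0.00435), against 0.69 and 0.82 in the later stages. The forkhead probe that fell in the mean, Nve_S44937337_469, stood at -3.84 ± 0.25 in buds (adjusted p = 9.09e-04), the lowest value of any called probe there, while 3 other forkhead probes rose. The Wnt probe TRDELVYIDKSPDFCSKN reached 2.09 ± 0.17 and the thrombospondin repeat probe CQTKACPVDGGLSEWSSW 2.51 ± 0.17.

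Tubulin and EGF-like probes were called in both directions in buds. Of 29 tubulin probes 7 rose and 4 fell (10 and 12 adjusted over the list alone), with a median of -0.16 and a mean of 0.10, and the alpha tubulin probe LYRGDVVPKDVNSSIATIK stood at 2.47 ± 0.20 (adjusted p = 0.00179). Of 38 EGF-like probes 4 rose and 4 fell, with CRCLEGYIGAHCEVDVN at -2.63 ± 0.18. Camera called core histones (median 0.28, adjusted p = 1.03e-05), Sox and HMG box (0.66, adjusted p = 0.00200), homeodomain and the thrombospondin family (both adjusted p = 0.0201, the second 0.0325 without its EGF-like matches). With an estimated correlation each had an adjusted p of 0.710.

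Across all probes in buds 3198 were called, 1847 higher and 1351 lower. The highest were SB_54521_199 at 3.96 ± 0.19 (15.6-fold, adjusted p = 4.31e-04) and Nve_S45036911_906 at 3.88 ± 0.19, and next to the forkhead probe the lowest was Nve_S45001308_616 at -3.63 ± 0.23, well above background in the tentacle channel on 1 of 2 arrays. The count was 9521 under median centring (8830 higher, 691 lower, median of all probes 0.27), 0 of 2819 at an unadjusted p under 0.05 with arrays scaled to equal spread in limma, 791 from the buds arrays alone and 1017 at 2-fold or more, and the share of higher calls was 57.8%, against 92.7% under median centring and 67.9% with Agilent's processed signals. Without buds array 1 or 2 it was 7909 or 5367, and without either mature array, or on slide 1 alone, it was 1365.

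In growing tentacles, single probes of homeodomain proteins, thrombospondin repeats and alpha tubulins were called higher than in the body column, but the thrombospondin family, with 5 of 28 probes higher and 1 lower, was not called by camera (adjusted p = 0.0785). Ratios on growing array 2 lay closer to 0 than on the others (median absolute log2 ratio 0.0392, against 0.119 to 0.198), a limit on the size of the ratios given for this stage. Of 36 homeodomain probes 12 rose and 4 fell. The highest was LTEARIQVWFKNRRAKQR, which matched the Pax6 query, at 1.69 ± 0.19 (adjusted p = 0.00641). The lowest was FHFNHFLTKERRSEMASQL at -2.28 ± 0.12 (adjusted p = 6.12e-04). Each SE here is that of a 2-array mean, with the spread taken from the arrays of all stages. Of 29 tubulin probes 7 rose and 1 fell, with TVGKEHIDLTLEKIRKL and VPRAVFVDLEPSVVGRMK, both alpha, at 1.71 ± 0.13 and 1.71 ± 0.08. Of 29 C2H2 probes 5 rose and 0 fell (5 and 1 adjusted over the list alone, with limma as the test), up to 1.79 ± 0.21 for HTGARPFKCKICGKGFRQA. The thrombospondin repeat probe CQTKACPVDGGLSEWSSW stood at 2.57 ± 0.17, the Wnt probe at 1.62 ± 0.17 and the EGF-like probe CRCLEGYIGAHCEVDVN at -2.24 ± 0.18.

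Camera called 5 families higher in growing tentacles, namely homeodomain (median 0.24) and tubulin (0.15, both adjusted p = 0.00126), Sox and HMG box (0.42, adjusted p = 0.00501), core histones (0.08, adjusted p = 0.00923) and EF-hand proteins (0.27, adjusted p = 0.0119). With an estimated correlation core histones had an adjusted p of 0.875 and the other 4 an adjusted p of 0.765.

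Across all probes in growing tentacles 1432 were called, 903 higher and 529 lower. The highest were SB_3275_95 at 3.97 ± 0.34 (adjusted p = 0.00256) and Nve_S45019666_1090 at 3.78 ± 0.26 (adjusted p = 0.00125), the lowest SB_135_218 at -3.47 ± 0.10 (adjusted p = 4.37e-04) and SB_10096_111 at -3.20 ± 0.23 (adjusted p = 0.00148). The count was 3794 once spots beside bright specks were left out (a choice made after the counts had been seen; 1430 probes were called both ways), 3903 with no background correction, 3433 with Agilent's processed signals (73.2% higher, against 63.1%), 2828 with the authors' ratios, 4216 under median centring (96.8% higher, median of all probes 0.13), 714 at 2-fold or more, and 0 of 8802 at an unadjusted p under 0.05 with arrays scaled to equal spread in limma. Without growing array 1 or 2 it was 246 or 657, without either mature array, or on slide 1 alone, 602, and without either or both buds arrays 3096.

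In mature tentacles, 15 of 36 homeodomain probes rose and 5 fell, with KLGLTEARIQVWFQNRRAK, which matched the Pax6 query, at 1.73 ± 0.17 (SE of a 2-array mean, with the spread from all 6 arrays; adjusted p = 0.00423) and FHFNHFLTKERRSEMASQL at -2.39 ± 0.12 (adjusted p = 6.48e-04). Of 28 probes of the thrombospondin family 9 rose and 2 fell (8 of 26 and 2 without EGF-like matches), the highest being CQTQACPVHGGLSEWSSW and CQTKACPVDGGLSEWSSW, at 2.10 ± 0.15 and 2.10 ± 0.17. Of 29 tubulin probes 9 rose and 2 fell, with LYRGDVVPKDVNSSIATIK at 1.91 ± 0.20 and the beta tubulin stretch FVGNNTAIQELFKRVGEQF at -1.31 ± 0.09. Of 38 EGF-like probes 4 rose and 6 fell, with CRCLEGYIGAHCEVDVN at -2.82 ± 0.18 (adjusted p = 0.00109), a median of 0.09 and a mean of -0.08. Proteases went both ways, with the astacin metalloprotease probe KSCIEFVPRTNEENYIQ at 1.80 ± 0.26 and the papain-like probe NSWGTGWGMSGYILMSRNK at -1.66 ± 0.10 (adjusted p = 9.76e-04).

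Camera called 6 families higher in mature tentacles, namely core histones (median 0.18, adjusted p = 0.00194), tubulin (0.21, adjusted p = 0.00480), the thrombospondin family (0.11, adjusted p = 0.0144, and 0.0150 without its EGF-like matches), Sox and HMG box (0.50, adjusted p = 0.0149), homeodomain (0.15, adjusted p = 0.0202) and EF-hand proteins (0.40, adjusted p = 0.0210). It called small GTPases (median -0.21, adjusted p = 0.0150) and protein kinases (-0.05, adjusted p = 0.0202) lower, medians that in the mean of the stages turned sign under median centring. With an estimated correlation core histones, small GTPases and protein kinases had an adjusted p of 0.871 and the other 5 an adjusted p of 0.853.

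Across all probes in mature tentacles 2883 were called, 1719 higher and 1164 lower. The highest were JGI_85362_297 at 3.19 ± 0.19 (adjusted p = 9.17e-04) and SB_3275_95 at 3.07 ± 0.34 (adjusted p = 0.00540), the lowest SB_18914_30 at -3.11 ± 0.39 (adjusted p = 0.00749) and SB_135_218 at -3.07 ± 0.10 (adjusted p = 5.45e-04). The count was 9557 under median centring (8975 higher, 582 lower, median of all probes 0.24), 0 of 3427 at an unadjusted p under 0.05 with arrays scaled to equal spread in limma, 7647 from the mature arrays alone and 1073 at 2-fold or more, and the share of higher calls was 59.6%, against 93.9% under median centring and 74.9% with Agilent's processed signals. Without mature array 1 or 2 it was 88 or 80, and without either or both buds arrays 7106.

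The 3 stages shared many of these probes. Of 4312 called in at least 1 stage, 1156 (26.8%) were called in all 3 in one direction, 761 higher and 395 lower, where independent lists of these sizes would share 2.94 and 0.852. Among them were the homeodomain probe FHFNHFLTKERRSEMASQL, the Wnt probe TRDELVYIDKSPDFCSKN, the thrombospondin repeat probe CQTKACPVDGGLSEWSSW and the EGF-like probe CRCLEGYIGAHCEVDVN. A further 2268 probes were called in exactly 1 stage, which does not show that the stages differ there, and 25 had opposite calls in 2 stages. Pearson's correlation between stages was 0.838 for buds and growing, 0.789 for buds and mature and 0.869 for growing and mature (Spearman's 0.617, 0.640 and 0.664), across probes, which are not independent replicates. The stages share no RNA, but each ratio carries the dye effect of its probe, which would be shared. The 3 lists also come from one fit with one estimate of the spread for each probe, which favours the same probes in each list. The numbers for independent lists are therefore no test of the overlap. The number in all 3 stages was 2055 once spots beside bright specks were left out, 1740 with the authors' ratios and 3778 under median centring.

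**Figure D2:**
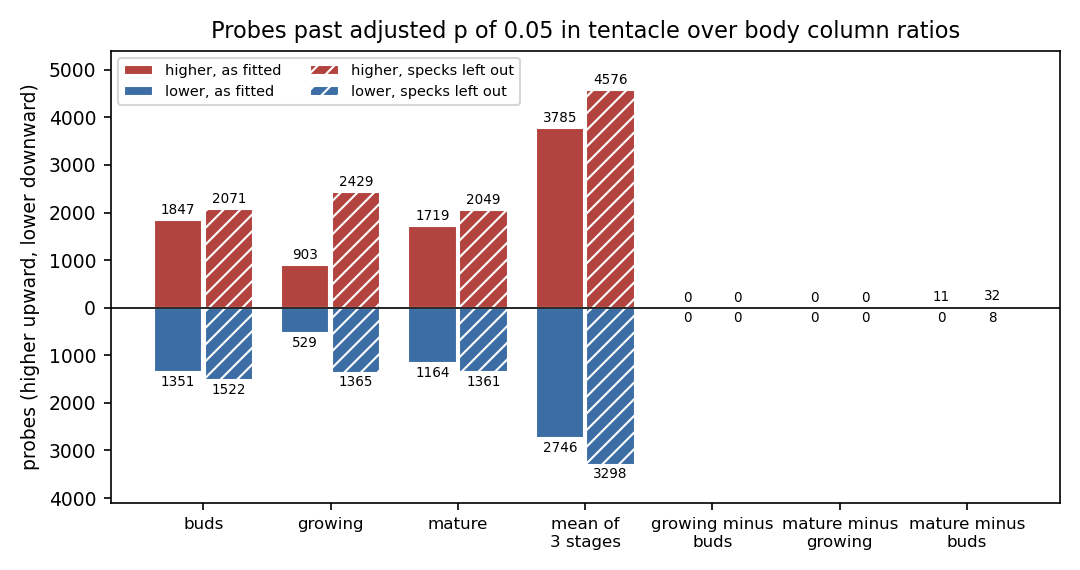
Number of probes called higher (upward) or lower (downward) by limma at an adjusted p of 0.05 in each stage, in the mean of the 3 stages and in differences between stages, as fitted (solid) and with spots beside bright specks left out (hatched). The ratios against the body column give 1432 to 6531 calls as fitted, and the differences between stages at most 11.

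Differences between stages were tested on the ratios themselves. Between growing tentacles and buds 0 probes were called by limma, with 1702 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0803, and 12 were called with an intensity trend and robust variances. The forkhead probe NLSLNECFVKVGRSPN--GKG differed by 2.16 ± 0.36 (adjusted p = 0.453; its growing ratio was -1.69, and -2.32 once spots beside bright specks were left out) and the T-box probe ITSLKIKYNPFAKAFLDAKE by -1.54 ± 0.34 (adjusted p = 0.617), and so were not called. Camera called the ratio of tentacle over body column higher in growing tentacles than in buds for tubulin (median difference 0.31, adjusted p = 2.38e-05). For core histones it called the ratio lower (-0.13, adjusted p = 0.0165). With an estimated correlation the adjusted p was 0.633 and 0.823. A change of the body column alone would also move such a ratio. Without buds array 1 or 2 the count of probes was 815 or 361.

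Between mature and growing tentacles 0 probes were called by limma as fitted and under each of the 24 alternatives. As fitted, 911 had an unadjusted p under 0.05, and the smallest adjusted p was 0.306. Some alternatives could give no other count, since Aquantile scaling leaves the ratios unchanged and a 2-fold cut can only remove calls. The papain-like protease probe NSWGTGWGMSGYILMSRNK differed by -1.40 ± 0.14 (adjusted p = 0.485). Camera called the ratio of tentacle over body column of small GTPases lower in the mature than in the growing stage (median difference -0.13, adjusted p = 0.00613). With an estimated correlation the adjusted p was 0.896.

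Between mature tentacles and buds 11 probes, in 10 groups by shared bases, were called, and in all 11 the ratio rose. All 11 were lower in the tentacle than in the body column of buds (median log2 ratio -1.76), while their median was -0.31 in growing tentacles. In mature tentacles 5 of the 11 were not well above background in at least 1 channel on either array, so their ratios there were not fully measured. The other 6 had ratios between -0.28 and 1.00 (median 0.25, against -2.42 in buds), and 3 of them were called higher than the body column. The normalized body column signal was lower in mature animals than in buds for 10 of them (median difference -3.16) and the tentacle signal for 9 (-0.99). These levels are bounds where the signal was not well above background on either mature array, as in the body column for 3 of the 11 and in the tentacle for 4. The largest differences were those of JGI_231713_78, 3.33 ± 0.21, which went from -3.58 in buds through -1.09 to -0.26, and of Nve_S45028575_144, 2.94 ± 0.22, from -3.13 through -2.23 to -0.19. With spots beside bright specks left out, their growing ratios were -1.63 and -2.59. All 11 had an adjusted p of 0.0437 and none matched a family. Of the family members the nearest were the papain-like probe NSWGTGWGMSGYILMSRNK (-1.45 ± 0.14, adjusted p = 0.0632) and the forkhead probe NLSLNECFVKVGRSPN--GKG (3.11 ± 0.36, adjusted p = 0.0851), the second of which was called once spots beside bright specks were left out (adjusted p = 0.0111). The tentacle signal of this forkhead probe was well above background on 0 of 2 mature arrays, so its mature ratio and the difference are bounds, not exact values. The same holds for the papain-like probe, whose tentacle signal was well above background on 0 of 2 buds arrays.

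Camera called the ratio of tentacle over body column of tubulin higher in the mature stage than in buds (median difference 0.17, adjusted p = 0.0132). Adjusted over the list alone, this ratio was higher for 7 of 29 probes and lower for 1. With an estimated correlation the adjusted p was 0.845. The 11 calls became 40 (32 higher, 8 lower, 10 of them shared) with the specks left out, 29 with no background correction, 18 with an intensity trend and robust variances, 6 with the stricter dim filter or after removal of a GC trend, 2 with Agilent's processed signals, and 0 in limma under median centring, with scaled arrays, from the arrays of these stages alone and with the authors' ratios (1722, 1003, 1911 and 2529 at an unadjusted p under 0.05). Without buds array 1 or 2 the count was 126 or 2906, and without any 1 of the other 4 arrays it was 0, while slide and mature stage cannot be told apart.

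**Figure D3:**
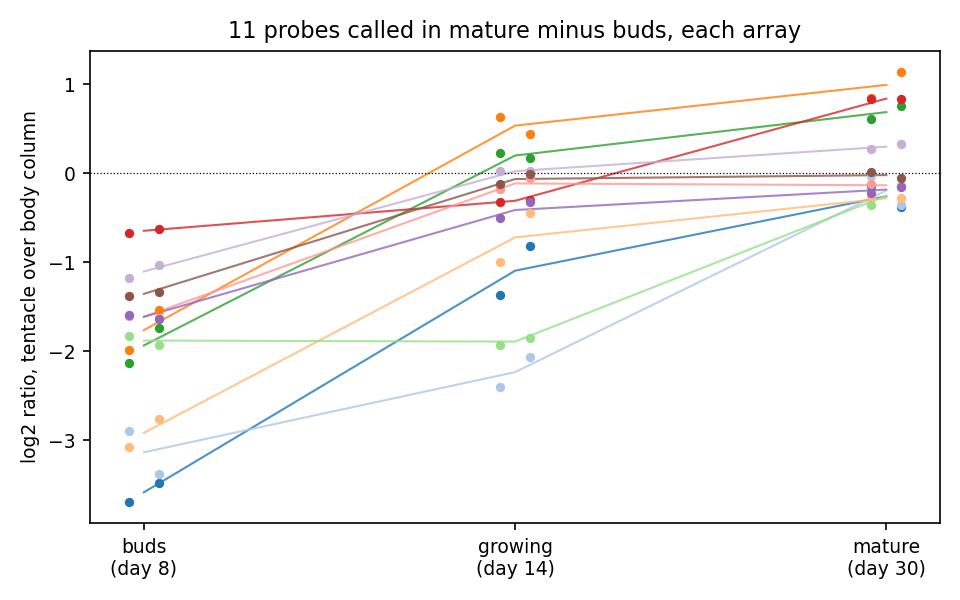
Log2 ratios of tentacle over body column for the 11 probes called between mature tentacles and buds, with points for single arrays and lines through the stage means. All 11 lie below 0 in buds (median -1.76). In mature tentacles only 6 are well above background in both channels on both arrays (median 0.25), and the points of the other 5 there are not exact.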

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

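Chosen only after the results were seen were the tests of exchanged labels, of place on the slide, of the slide and the low signal of the mature arrays, and of dye effects, and the alternative without spots beside bright specks.

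The ratio of tentacle over body column differed between mature tentacles and buds, by a test of the difference itself, for 11 probes, most of all for JGI_231713_78, whose ratio was higher in mature tentacles by 3.33 (limma, adjusted p = 0.0437, 2 arrays against 2), and Nve_S45028575_144, higher by 2.94. The slide of the mature arrays as the whole cause would leave growing minus buds, both on the other slide, near 0, and its median over these probes was 1.25 with 10 of 11 the same way (spots beside specks left out), but the buds arrays enter both differences and part of this may come from the choice of probes. With probes chosen without buds array 1 or 2, and growing set against the array left out, the median was 0.49 (97 of 126 the same way) or -0.12 (1162 of 2906), so slide and stage cannot be told apart. Of the 11, 6 were well above background in both channels on both mature arrays, and 3 of these were called higher than the body column there. A pull of dim ratios towards 0 would not take a ratio from below 0 to above it. These 3 therefore argue against signal near background as the whole cause. It stays open for the rest, since the flag does not show a ratio to be free of the offset's pull. Among the rest were JGI_231713_78 and Nve_S45028575_144, with mature ratios of -0.26 and -0.19. The count depends on the buds arrays and on the processing (2906 without buds array 2, 0 with the authors' ratios in limma, where 2529 had an unadjusted p under 0.05), so a stage difference, mixed with slide, may account for these probes but remains a hypothesis.

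By Pearson's correlation the 2 buds arrays stood at 0.544, against 0.852 and 0.869 within the other stages, and buds array 1 lay further from the arrays of those stages (0.495 to 0.708) than buds array 2 (0.706 to 0.827). By Spearman's the buds pair stood at 0.217, against 0.669 and 0.698. An exchange of labels between buds array 2 and mature array 1 would raise the correlation within both stages, but it changed that of the mature pair by -0.114 and that of the buds pair by -0.0485. Removing a smooth trend over the array surface changed the buds correlation by -1.35e-04 and removing the GC trend by 0.00148, so neither accounts for the gap. The deviations of arrays on different slides that share a place correlated at 0.154 and 0.347, but with 2 arrays per stage deviations mirror each other and pairs that share no place gave the same values, so an effect of place cannot be told apart. The intercepts of the spike-in probes in Agilent's log10 ratios were lowest on buds array 1 (-0.195) and highest on buds array 2 (0.319), with mature array 1 next (0.162). Whether such a difference in channel balance plays a part after loess was not tested. A difference between the pooled larvae of the 2 samples was not tested either, and both stay open.

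The mean of the stages called 6531 probes, 20.9% of those tested. After the GC trend of each array was removed 96.0% of them were still called, and the rank correlation of ratio and GC content was 0.0736, which argues against GC content as the whole cause. Of 32 patterns of turned array signs only 1, the real one, gave as many calls, and the highest other gave 597. This argues against chance agreement of the arrays, but 32 patterns are too few to exclude it. A dye effect shared by all arrays would also favour the real pattern. Dye effects of single probes remain open, since the dyes were never exchanged and the 10 spike-in probes differ in sequence from the called probes. The spike-in probes scattered about each array's fitted line of observed on expected log2 ratios with a mean SD of 0.174. The median absolute log2 ratio of called probes was 0.42. That SD leaves out the slope and intercept of the line, and the intercepts ran from -0.195 (buds array 1) to 0.319 (buds array 2) in log10 units. A difference between tissues may account for these calls, but it was not tested apart from the dyes.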

How the results depend on the processing

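Alternatives chosen only after results were seen were the removal of GC and surface trends, the averaging of overlapping probes, the leaving out of both buds arrays, of spots beside bright specks and of the EGF-like matches of the thrombospondin family. None of 406 values of named probes and 161 family tests reversed a called direction, but not all of them were open to a reversal. Only a family called as fitted has a called direction, which held for 4 of the 23 tested in the mean of the stages. For named probes, Aquantile scaling and the 2-fold cut leave the ratio and its sign unchanged. Of the values of named probes 43 lost their call, and of the family tests 8 lost and 9 gained one. A family is counted anew under each alternative. The named probes here were those given by probe name, with the largest ratios of their comparison. Family members given only by translated sequence were not part of this check. Counts of family members did turn: under median centring protein kinases went from 2 higher and 10 lower to 22 and 3, and small GTPases from 1 and 4 to 14 and 1. Counts stayed within 1.5 times under 15 of 24 alternatives for buds, 10 of 25 for growing, 15 of 24 for mature, 14 of 22 for the mean, 21 of 24 for growing minus buds, 24 of 24 for mature minus growing, 6 of 23 for mature minus buds, 5 of 7 for families and 1 of 4 for the overlap. Some of these could not move a count, such as Aquantile scaling, or the 2-fold cut where no probe was called. Except where said, the cause of a changed count was not tested.

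Median centring gave 9521 calls in buds, 4216 in growing, 9557 in mature, 15822 in the mean, 3778 in all 3 stages and 0 in mature minus buds. Scaling of arrays gave 0 in buds, growing and mature, 2100 in the mean and 0 in mature minus buds. It multiplied growing array 2 by 4.17. Agilent's processed signals gave 3433 in growing and 2 in mature minus buds, no background correction 3903 and 29, and the authors' ratios 2828 and 0, with 1740 in all 3 stages. Leaving out specks gave 3794 in growing, 40 in mature minus buds and 2055 in all 3 stages. Since 96 of these 189 spots lay on growing array 2, the rise in growing came with a changed background estimate there. Own arrays alone gave 791 in buds, 7647 in mature and 0 in mature minus buds. Slide 1 alone gave 1365 in buds and 602 in growing, and without both buds arrays growing had 3096 and mature 7106. A log2 ratio of at least 1 left 1017 in buds, 714 in growing, 1073 in mature and 885 in the mean, by construction. An intensity trend with robust variances gave 12 in growing minus buds and 18 in mature minus buds. The stricter dim filter and GC removal each gave 6 in mature minus buds. Unadjusted counts beside the zeros stand with each comparison. Of families, 0 were called with an estimated correlation and 8 by fry.

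Leaving out 1 array gave 1365 to 7909 calls in buds, 246 to 3096 in growing, 80 to 7106 in mature, 3169 to 12278 in the mean, 0 to 815 in growing minus buds, 0 to 0 in mature minus growing and 0 to 2906 in mature minus buds. The highest came without buds array 1 in buds, the mean and growing minus buds, without either buds array in growing and mature, and without buds array 2 in mature minus buds. The lowest came without growing array 1 in growing, mature array 2 in mature, mature array 1 in the mean and either mature array in buds. A lone array of a stage was taken to vary like the others. Replicate numbers shared by the stages do not pair samples (correlations of deviations -0.05, -0.35 and 0.15), and with a replicate block limma called 2198, 1030, 1999 and 5207 probes in buds, growing, mature and mean and 0 in each difference (2109 at an unadjusted p under 0.05 in mature minus buds). Not run were the mean of a gene's probes, for want of gene names, and the slide as a random block, which could not be estimated. Own arrays alone are the fit itself for the mean. Signal limits dim probes, since 23420 of 31244 were well above background in both channels on every array.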

Other observations

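Of the values below, only those without spots beside bright specks come from an alternative chosen after results had been seen; the members named are those the rule for families takes.

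Smaller families held probes with high or low ratios in the mean of the stages, all with one sign on all 6 arrays. A probe of the LDL receptor class A repeat, a module of lipoprotein receptors and other extracellular proteins, rose by 1.40 ± 0.07 (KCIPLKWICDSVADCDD, adjusted p = 8.17e-05), the 1 of 6 measured that was called. A stretch like that of voltage-gated potassium channels, which shape the firing of nerve and muscle cells, rose by 1.43 ± 0.18 (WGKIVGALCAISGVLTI, adjusted p = 0.00338), 1 of 3 measured. An ankyrin repeat probe rose by 1.27 ± 0.13 (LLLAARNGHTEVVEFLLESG). Proteases divided. Of 2 trypsin-like probes HKCGGALIDREWVV rose by 1.26 ± 0.08 and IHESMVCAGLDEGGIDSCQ fell by 1.40. Of 5 astacin probes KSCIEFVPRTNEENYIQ, well above background in the body column on 3 of 6 arrays, rose by 1.19 ± 0.15 and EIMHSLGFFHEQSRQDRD fell by 0.80. Of 7 papain-like probes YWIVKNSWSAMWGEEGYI rose by 0.77 ± 0.09 and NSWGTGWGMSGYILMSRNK, in the tentacle well above background on 4 of 6 arrays, fell by 0.71. Actin, the filament protein of muscle and cell cortex, also divided, with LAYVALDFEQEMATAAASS at 0.95 ± 0.09 and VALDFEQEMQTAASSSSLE at -0.72 ± 0.10, 9 of 11 probes not called, and a family median of -0.22 that became 0.48 under median centring, where 6 were called higher and 2 lower. With arrays scaled to equal spread limma called 0 LDL receptor repeat, trypsin-like and actin probes (2, 1 and 7 at an unadjusted p under 0.05). It called 1 astacin, 1 potassium channel and 2 ankyrin probes higher and 1 papain-like probe lower. The 1 measured probe that matched a myosin head, which muscle and other myosins share, fell by 0.32, but under median centring its value was -0.17 and was not called.

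Of 12 probes of the translation machinery 2 rose and 0 fell by limma, at 0.33 ± 0.06 and 0.25 ± 0.05, with a family median of -0.01 that became 0.81 under median centring, where 11 were called higher. Of 4 probes of mitochondrial respiration 0 were called by limma, with a median of -0.05 that became 0.68 under median centring, where 3 were called higher. Of 5 HSP70 probes, which report chaperones, 2 rose and 1 fell (with scaled arrays 0 were called by limma, with 5 at an unadjusted p under 0.05), with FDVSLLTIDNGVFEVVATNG at 0.78 ± 0.08. Neither of the 2 probes matching GFP-like proteins was among those measured.

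With spots beside bright specks left out, 40 probes differed between mature tentacles and buds, 32 higher and 8 lower, with adjusted p from 0.0111 to 0.0494. Of these 36 had a ratio below 0 in buds, and 32 were called lower in the tentacle than in the body column there. In mature tentacles 11 of the 40 were called higher than the body column and 9 lower. The normalized body column signal was lower in mature animals than in buds for 32 of them (median difference -2.24) and the tentacle signal for 29 (-0.82), and on neither mature array were 10 well above background in the body column and 11 in the tentacle, so those levels are bounds. Of the 40, 25 were well above background in both channels on both mature arrays. The forkhead probe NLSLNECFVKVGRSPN--GKG was among the 40, at 3.10 (adjusted p = 0.0111), but its tentacle signal was well above background on 0 of 2 mature arrays, so this difference is a bound.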
